A study of Gallus gallus with 8 samples.

How the data were processed

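Single-cell RNA libraries of dissected chick hypothalamus were made by the authors from methanol-fixed, rehydrated cells with 10x chemistry 3.0 and sequenced on an Illumina NextSeq instrument, per the series design text. The labels give the tissue, the Hamburger-Hamilton stage and mixed sex for each of 8 samples, and samples were grouped by stage and replicate number from their titles. The deposited matrix of HH18/19 replicate 1 held raw UMI counts per gene and barcode, unfiltered and not normalized; the authors made it with Cell Ranger against Ensembl release 95 of the chick genome build GRCg6a, per the series design text and the submitters' processing notes. Those notes also name Seurat 3, and no output of it was used here. The whole-number values and the number of barcodes (6794880 possible, 919487 with a UMI) were checked in the matrix itself. Count matrices of the other 7 samples were not used here, so the planned look across stages was not made. The design text gives HH8 for a pair of samples and names no HH10 sample, while the labels name HH10, and the labels were followed.

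Of 24356 genes, 13688 had a symbol and 10668 only an Ensembl identifier. Of 353 genes in the fixed lists and marker sets, 316 were matched by name, 3 of them through synonyms in a RefSeq gene table of another assembly, GRCg7b, that was used for names only: CRABP1 (CRABP-I in the matrix), LHX2 (LH-2A) and MEIS2 (Meis2a.2). No coordinates or chromosomes were used, and no annotation of the build was used here. The planned ratio of Z-linked to autosomal expression was therefore not run. W-linked genes were taken by their names: Wpkci-7, SPIN1W and NIPBLL.

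A barcode was called a cell when its UMI total reached the 99th percentile of the 3000 largest totals divided by 10 (2415 UMIs), with at least 500 genes and at most 20% mitochondrial UMIs. The design text gives 8000 to 12000 cells loaded per run, and 4236 barcodes passed. Droplets with 100 to 400 UMIs (72237 barcodes) gave the profile of free RNA. Doublets were simulated by adding random pairs of cells, 2 for each cell, and each cell was scored by the share of simulated doublets among its 30 nearest neighbours. The score threshold of 0.8, set by Otsu's method on the simulated doublets, took 81.0% of these and removed 462 cells with a median of 10691 UMIs, against 5214.5 UMIs in the cells kept. Doublets of like cells are not found in this way. Cells with at least 10% globin UMIs were set aside as erythroid.

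Counts were scaled to 10000 per cell and log transformed, and 2000 variable genes were chosen by the variance of Pearson residuals (theta of 100, genes in at least 10 cells). All fixed list genes, mitochondrial genes, the W-linked genes and 14 genes over 4 times higher in cells with 6 or more than in cells with 3 or fewer Wpkci-7 UMIs were left out of these features. Marker genes used for naming, NKX2-1, PAX6 and SIX6 among them, were allowed. Leiden clustering at a resolution of 1.0 ran on a shared-neighbour graph (15 neighbours) of 30 principal components with seed 1. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.

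The marker sets covered 17 cell types: tuberal progenitor, mammillary progenitor, supramammillary or floor plate, prethalamus, thalamus or more caudal brain, telencephalon, optic, neural progenitor, neurogenic progenitor, neuron, mesenchyme, endothelium, erythroid, macrophage, surface ectoderm, neural crest and notochord. A marker was raised in a cluster when it had at least 10 UMIs and the lower bound of its CPM was over 1.5 times its CPM in all other cells. Clusters with 3 raised neuron markers were neuron-like, those with 3 raised tuberal markers and no more of any other region tuberal-like, and those with 3 raised supramammillary markers, among them a required marker that is not reported here, supramammillary-like.

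UMIs were summed per class. CPM values carry exact Poisson intervals, shares exact Clopper-Pearson intervals and ratios of CPM exact conditional binomial intervals, all at 95% and for counting error only. A gene with 0 UMIs in a class was set against a floor of 3 UMIs. The level that free RNA adds to a class was the share of the gene in free RNA times 257.2 UMIs over the median UMIs of the cells, and a fold is marked near background where the lower bound of the lower level did not exceed it, a rule chosen after the data were seen. Lists were also taken without each measured member, and named genes without each cluster of a class, and those of these values that bear most on a stated direction are given. The 16 lists fixed before the data were examined were SHH, BMP, WNT, FGF and Notch signalling, retinoid and thyroid hormone, S and G2/M cycling, cell cycle exit, hypothalamic readout, prethalamic readout, midbrain and hindbrain, neuropeptide and transmitter, neuronal differentiation, early response and heat shock, glycolysis and hypoxia, and adhesion and guidance. A list member was measured when it had at least 50 UMIs over both classes, and higher or lower refers to its value alone. The median of a list was set against 10000 random lists of the same size drawn from 20 bins of expression. Named genes followed a rule fixed in advance. It took the 2 highest and 2 lowest members of each list with at least 50 UMIs and an interval that excluded a ratio of 1, at most 30 in all. To these it added the 5 highest and 5 lowest genes outside the lists that were not clustering features, and always SHH, FGF10, NKX2-1, PAX6 and SIX6. Genes named as examples beside these (PTCH1, JAG1 and BTG2), and values of single clusters, were chosen after their values were seen. For co-detection each cell was thinned to 2400 UMIs, below the smallest cell, and counts were averaged over 100 random thinnings.

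The intervals were tested on simulated counts with 200 genes changed by known folds. These counts were drawn from the Poisson model that the intervals assume. The test therefore checks the computation only, and cannot show how the intervals do with spread between cells or with other cluster borders. Over cluster 3, the supramammillary-like and the neuron-like cells, 4.22%, 3.53% and 4.17% of the intervals of unchanged genes excluded a ratio of 1. Among the 50 genes of each true fold in these comparisons, 90.0% to 100% of the intervals held the true fold. Clustering recovered all 14 simulated clusters, an easy case because the simulated cells varied only by counting error around cluster means.

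Alternatives fixed before the data were examined were a minimum of 1000 genes, at most 10% mitochondrial UMIs, a threshold from the 6000 largest totals, doublets kept, 4000 variable genes, resolutions of 0.6 and 1.6, seed 2, naming markers left out of the features, free RNA subtracted, a mean of per-cell CPM, UMIs split between clustering and values, co-detection without thinning or with 2 UMIs, and other minimums of W-linked UMIs. Choices made after the data were seen were the range of UMIs for empty droplets, the removal of erythroid cells, the removal of genes that follow Wpkci-7 from the features, the rule for a raised marker, the required marker of the supramammillary-like class, cluster 3 as stand-in for prethalamus, the mean over thinnings in place of 1 thinning, and the added alternatives named in the closing section.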

Results

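Single-cell RNA sequencing was used to follow the chick hypothalamus, the ventral part of the forebrain, through early development. The stages are given on the Hamburger-Hamilton (HH) scale, which orders chick embryos by their external form. The series held 8 samples in 6 stage groups, with 2 samples each at HH8 and HH18/19 and 1 each at HH10, HH13/14, HH15/16 and HH20/21. UMI counts (counts of unique molecular identifiers, which tag single RNA molecules) of 1 sample, HH18/19 replicate 1, were analysed. The other 7 samples were not analysed here, so no comparison between stages or replicates was made. All values below therefore come from 1 library of mixed sex, and no difference has a replicate check or was tested for significance. Intervals are exact 95% intervals and cover counting error only.

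The library held 49030338 UMIs over 24356 genes, spread over 919487 barcodes. A total of 4238 barcodes had at least 2415 UMIs, 4236 of them passed the limits on detected genes and mitochondrial UMIs, and 462 (10.9%) were removed as doublets. The 3774 cells kept included 2 erythroid cells, in which globin genes made up 68.2% and 70.9% of UMIs. The remaining 3772 cells had a median of 5213.5 UMIs, 2223 genes and 9.36% mitochondrial UMIs. With at most 10% mitochondrial UMIs in place of 20%, 2404 cells were kept. Free RNA, measured in droplets with 100 to 400 UMIs, averaged 257.2 UMIs per droplet, or 4.93% of the median cell. A gene with 0 UMIs in a class was set against a floor of 3 UMIs over the class, and the lower end of its exact interval is given beside that bound. Folds marked near background have a lower level whose interval reached down to what free RNA adds, so for these only the lower end of the interval bounds the fold in the cells. Levels are summed UMIs of a gene per 1000000 UMIs of the same cells (CPM).

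The cells fell into 14 clusters, which were named from fixed marker genes. Tuberal-like progenitors (clusters 1, 4, 6 and 11) carried NKX2-1, RAX, SIX6, CHRDL1 and SIX3 in varying sets, transcription factors and a secreted BMP antagonist of the tuberal hypothalamus, the region above the pituitary. They made up 1418 cells, or 37.6% (36.0 to 39.2%). Cluster 11 had neither NKX2-1 nor RAX raised, and had the optic marker PAX2 and the mesenchyme marker COL3A1 raised. Cluster 1 had the mammillary marker EMX2 and the notochord or prechordal markers NOTO and GSC raised. A supramammillary-like cluster (cluster 10) with raised LMX1B, FOXA1 and BARHL1 held 200 cells, 5.30% (4.61 to 6.07%). It also had the mesenchyme markers COL3A1 and POSTN raised, POSTN at 399.8 CPM against 9.06 CPM in all other cells. Neuron-like clusters (8, 9, 12, 13 and 14), with raised ELAVL4, STMN2, DCX and STMN4, held 592 cells, 15.7% (14.5 to 16.9%). Cluster 3, with raised PAX6 and OLIG2, transcription factors of prethalamic progenitors, held 411 cells, 10.9% (9.92 to 11.9%). The remaining clusters 2, 5 and 7 held 1151 cells, 30.5% (29.1 to 32.0%), and entered the comparisons below only where stated.

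No cluster had 3 or more raised markers of telencephalon, optic tissue, mesenchyme, endothelium, erythroid cells, macrophages, surface ectoderm, neural crest or notochord, and no cluster had 3 raised neural progenitor markers. Neurogenic progenitor markers were raised in neuron-like clusters 8 (NEUROD4, HES6 and GADD45G) and 9 (4 of 5 matched markers). Cluster 2 had 4 of the 7 matched markers of thalamus or more caudal brain raised (GBX2, IRX1, IRX2 and IRX3). Clusters 5 and 7 had 3 and 4 raised supramammillary or floor plate markers, FOXA2 and SPON1 among them, were not given that name, and held 8.99% and 6.79% of cells. No progenitor cluster reached 3 raised markers of prethalamus or of mammillary hypothalamus. Class sizes moved with the clustering: at a resolution of 0.6 the tuberal-like share was 15.1%, and with at most 10% mitochondrial UMIs the supramammillary-like share was 8.29%.

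**Figure D1:**
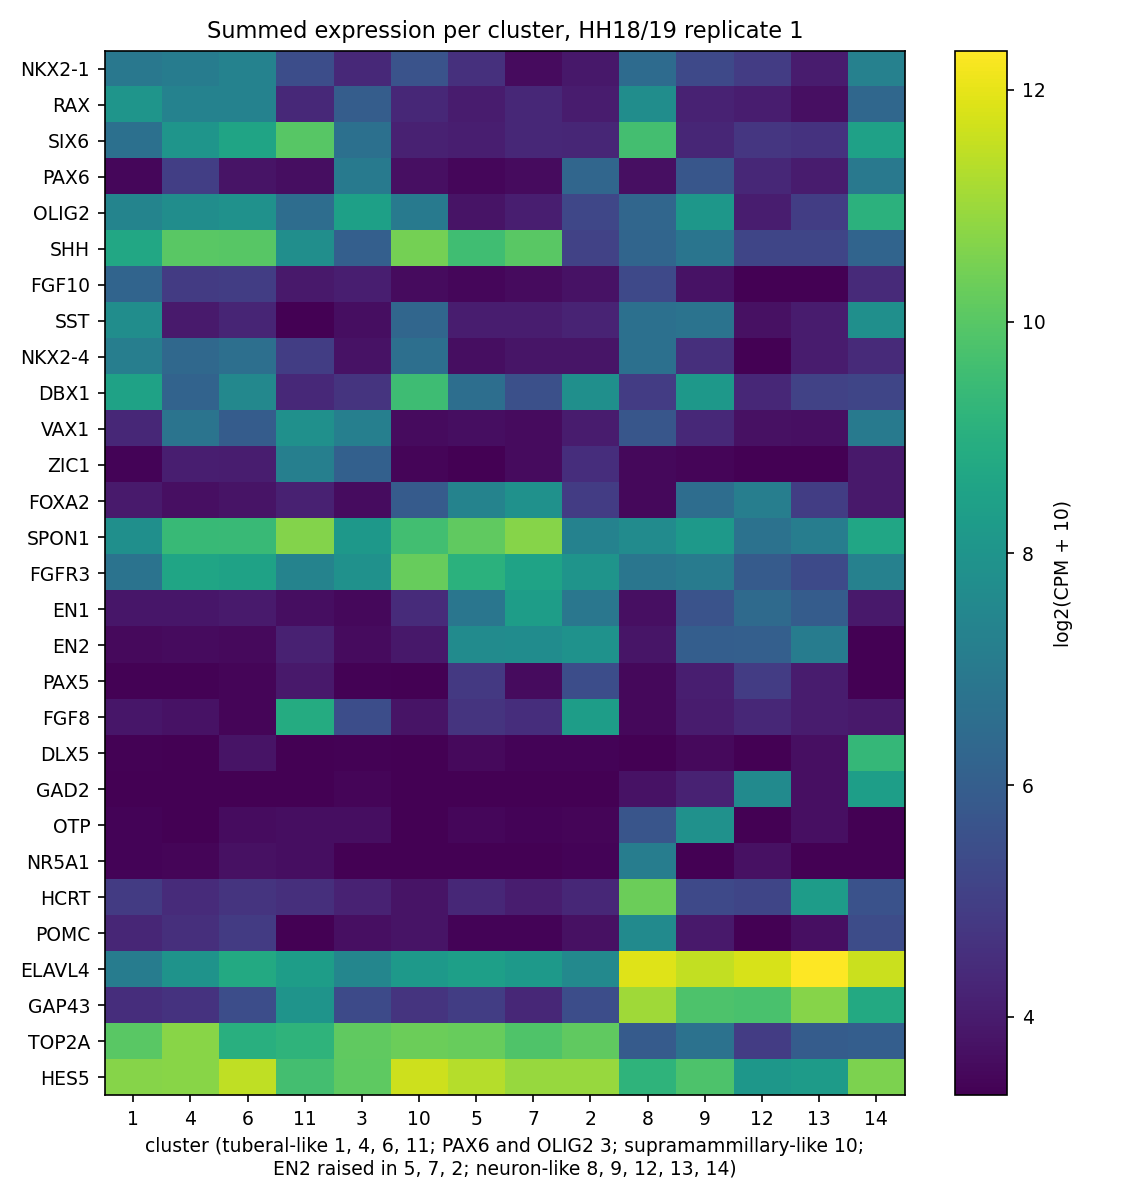
Summed expression of selected genes (vertical axis) in each of the 14 clusters (horizontal axis), as log2 of CPM (counts per 1000000 UMIs) plus 10, in HH18/19 replicate 1. SHH reached 1398 CPM in cluster 10 against 56.7 CPM in cluster 3, and EN2 reached 230.5 CPM in cluster 2 against 1.65 CPM in cluster 1.

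The title of the series relates hypothalamic cells to prethalamic-like progenitors, and the first comparison set these side by side. No progenitor cluster met the naming rule for prethalamus, so cluster 3 took its place, a choice made after the data were seen. Its raised markers included PAX6 and OLIG2 of prethalamus, NR2E1 of telencephalon, and LHX9 of thalamus. SHH (ENSGALG00000006379), the secreted morphogen of the ventral midline, was 11.9-fold (10.1 to 14.1) higher in tuberal-like progenitors, at 673 CPM against 56.7 CPM. FGF10 (ENSGALG00000014872), an FGF ligand of the developing infundibular region, was 6.16-fold (3.84 to 10.5) higher, at 42.2 against 6.85 CPM, but cluster 1 held 275 of its 350 UMIs, and without cluster 1 the ratio was 2.71 (1.604 to 4.82). The homeodomain genes DBX1 and NKX2-4 were higher at 228.4 against 15.6 CPM and at 104.7 against 3.42 CPM, of which free RNA would add 1.87 CPM for NKX2-4. Without cluster 1 the DBX1 ratio was 5.93 (4.29 to 8.41). ZIC1, a zinc finger transcription factor of the dorsal neural tube, was 5.92-fold (4.49 to 7.85) lower in tuberal-like progenitors, and NR2F2, a nuclear receptor, was 2.67-fold (2.42 to 2.94) lower, or 2.996-fold and 1.51-fold without cluster 1.

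Of the 10 measured SHH signalling genes, 5 were higher and 5 lower in tuberal-like progenitors. The summed list was higher by a log2 ratio of 1.497 (1.393 to 1.602), but its median member stood at -0.038, at percentile 21.3 of random lists matched on expression. SHH itself decided the sum: without it the log2 ratio was -0.27 (-0.40 to -0.14). The transcription factors of the Hedgehog pathway GLI1 and GLI2 were 4.62-fold (3.05 to 7.05) and 5.89-fold (3.72 to 9.51) lower in tuberal-like progenitors. The receptor gene PTCH1 stood at 51.9 against 57.4 CPM, a ratio of 0.905 (0.750 to 1.10). CDON, a coreceptor, was 2.22-fold (1.10 to 5.07) higher. The summed log2 ratio depended on the clusters and was 0.32 when clusters and values came from separate random parts of the UMIs and 1.98 at a resolution of 0.6.

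Of the 9 measured BMP signalling genes, 5 were higher in tuberal-like progenitors, with a log2 ratio of the sum of 0.38 (0.33 to 0.43) and a median of 0.41, at percentile 99.7. The ID genes, whose products block basic helix-loop-helix factors and which respond to BMP, went both ways. ID2 was 4.88-fold (3.78 to 6.40) and ID3 4.17-fold (3.13 to 5.68) higher, or 3.03-fold and 2.15-fold without cluster 1, while ID1 was 1.79-fold (1.70 to 1.87) lower at 577 against 1031 CPM. Without ID1 the log2 ratio of the list was 1.47 (1.385 to 1.55), but without ID4, which held 50.1% of its UMIs, it was -0.445 (-0.51 to -0.385), so the sign of the sum rests on ID4.

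WNT signalling genes were mostly lower in tuberal-like progenitors, 10 of 13, with a median of -0.32, at percentile 0.03 of random lists. The sum had the opposite sign, with a log2 ratio of 0.18 (0.10 to 0.26), because of SFRP2, a secreted Frizzled-related protein gene, and without SFRP2 it was -0.34 (-0.45 to -0.23). WNT7B, a ligand, was 3.35-fold (2.51 to 4.47) lower and AXIN2, a target of WNT signalling, 2.31-fold (1.27 to 4.15) lower, while the ligand WNT5A was 3.25-fold (1.57 to 7.78) higher. For FGF signalling, 6 of 11 genes were higher, with a log2 ratio of 0.27 (0.18 to 0.35) and a median of 0.41, at percentile 99.9. FGF19, a ligand gene, had 94 UMIs in tuberal-like cells and 2 in cluster 3, a ratio of 14.9 (4.01 to 124.8, near background), but 88 of the 94 were in cluster 1, without which it was 1.95 (0.349 to 19.8). The direction of the WNT and FGF sums turned under other processing: their log2 ratios were -0.14 and -0.14 with the cell threshold from the 6000 largest totals, -0.10 and -0.02 with doublets kept, and -0.06 and -0.24 with the UMIs split between clustering and values.

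Among the other lists, all 6 measured neuropeptide and transmitter genes were higher in tuberal-like progenitors, with a log2 ratio of 2.38 (2.07 to 2.71). SST, the somatostatin gene, held 58.9% of the UMIs of that list, and without it the ratio was 1.10 (0.76 to 1.46). SST was at 204.7 CPM in cluster 1 but at 5.76 and 8.93 CPM in clusters 4 and 6 and had 0 UMIs in cluster 11. Its level in cluster 3 was 2.66 CPM, and free RNA alone would add 2.33 CPM there. Without cluster 1 the SST ratio was 2.32 (0.977 to 6.36). POMC, the pro-opiomelanocortin gene, was 3.84-fold (1.87 to 9.15) higher. All 5 measured prethalamic readout genes, with ZIC1 and NR2F2 among them, were lower in tuberal-like progenitors, with a log2 ratio of -1.22 (-1.33 to -1.11).

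The hypothalamic readout list had 5 of 9 genes higher and a ratio of 0.77 (0.66 to 0.88), which was 0.056 (-0.058 to 0.17) without DBX1. VAX1, a homeodomain gene of the ventral forebrain, was 2.64-fold (2.29 to 3.04) lower. Notch signalling genes were higher in 8 of 10 cases with a log2 ratio of 0.46 (0.42 to 0.51), and the Notch target HEY1 was 6.19-fold (3.56 to 11.8) higher. Without HES5, the most abundant member, the Notch ratio was 0.095 (0.032 to 0.16). Adhesion and guidance genes were higher in 8 of 11 cases at 0.52 (0.42 to 0.62). The ephrin receptor EPHA7 was 2.83-fold (2.04 to 4.01) and the cadherin CDH6 4.06-fold (1.65 to 12.9) higher, and CDH7 was 2.04-fold (1.51 to 2.74) lower. In cells with 3 or fewer UMIs of the W-linked gene Wpkci-7 the CDH6 log2 ratio was -0.37. All of cluster 3 held only 5 CDH6 UMIs, so this opposite direction is not resolved.

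Of 6 retinoid and thyroid hormone genes 4 were higher, at 0.47 (0.29 to 0.65). The retinol transporter gene STRA6 was 1.93-fold (1.52 to 2.48) higher. ALDH1A3, which encodes a retinoic acid synthesising enzyme, was 3.23-fold (2.07 to 5.03) lower, and CRABP2, a retinoic acid binding protein gene, 1.72-fold (1.01 to 2.85) lower. In cells with 3 or fewer Wpkci-7 UMIs their log2 ratios were 0.89 and 1.35, but cluster 3 held only 70 such cells. All of cluster 3 had 44 ALDH1A3 and 25 CRABP2 UMIs, and these ratios have no interval, so a turn is not resolved. Of 7 neuronal differentiation genes 5 were lower at -0.45 (-0.62 to -0.28), among them NEFL, a neurofilament gene, 6.72-fold (4.92 to 9.27) lower, and ONECUT1, 1.97-fold (1.07 to 3.56) lower, while MYT1 was 2.54-fold (1.15 to 6.59) higher. Without NEFL the list stood at 0.011 (-0.19 to 0.21), and without cluster 6 the MYT1 ratio was 0.851 (0.331 to 2.45). The list stood at -0.58 in cells with 6 or more Wpkci-7 UMIs but at 0.16 in those with 3 or fewer. Small ratios were found for S and G2/M cycling genes at -0.067 (-0.091 to -0.043), cell cycle exit at 0.058 (-0.003 to 0.12), and glycolysis and hypoxia at -0.089 (-0.12 to -0.057), the last with a median of 0.022. Early response and heat shock stood at 0.052 (0.034 to 0.071), with EGR1, an immediate early gene, 1.90-fold (1.38 to 2.68) higher. No midbrain and hindbrain gene reached the 50 UMIs needed, and the summed list had 63 UMIs against 11, a log2 ratio of 0.86 (-0.076 to 1.93).

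Genes of the clustering set these clusters apart and are given as levels only. NKX2-1 (ENSGALG00000037632), a homeodomain gene required for the hypothalamus, was at 119.8 against 10.7 CPM. PAX6 (ENSGALG00000012123) was at 7.83 against 119 CPM and SIX6 (ENSGALG00000020359), a homeodomain gene of hypothalamus and eye, at 222.9 against 90.9 CPM. Outside the lists, the genes with the highest ratios in tuberal-like progenitors were F8 and NOTO, with 0 UMIs in cluster 3 and at least 6.13-fold and 5.60-fold higher against the floor (intervals from 4.83 and 4.40), 51 of the 53 NOTO UMIs being in cluster 1. These were followed by ENSGALG00000048793 (19.0-fold, 3.28 to 763.4), SYNPO2 (16.5-fold, 2.83 to 663.3) and KCTD15 (14.9-fold, 5.72 to 55.2), all 3 near background. The lowest were CLEC19A, SGK3, BCO2, ZNF503 and LRMDA, lower by 5.92-fold to 3.70-fold. Cells with 6 or more Wpkci-7 UMIs made up 75.9% of the tuberal-like cells and 81.3% of cluster 3.

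**Figure D2:**
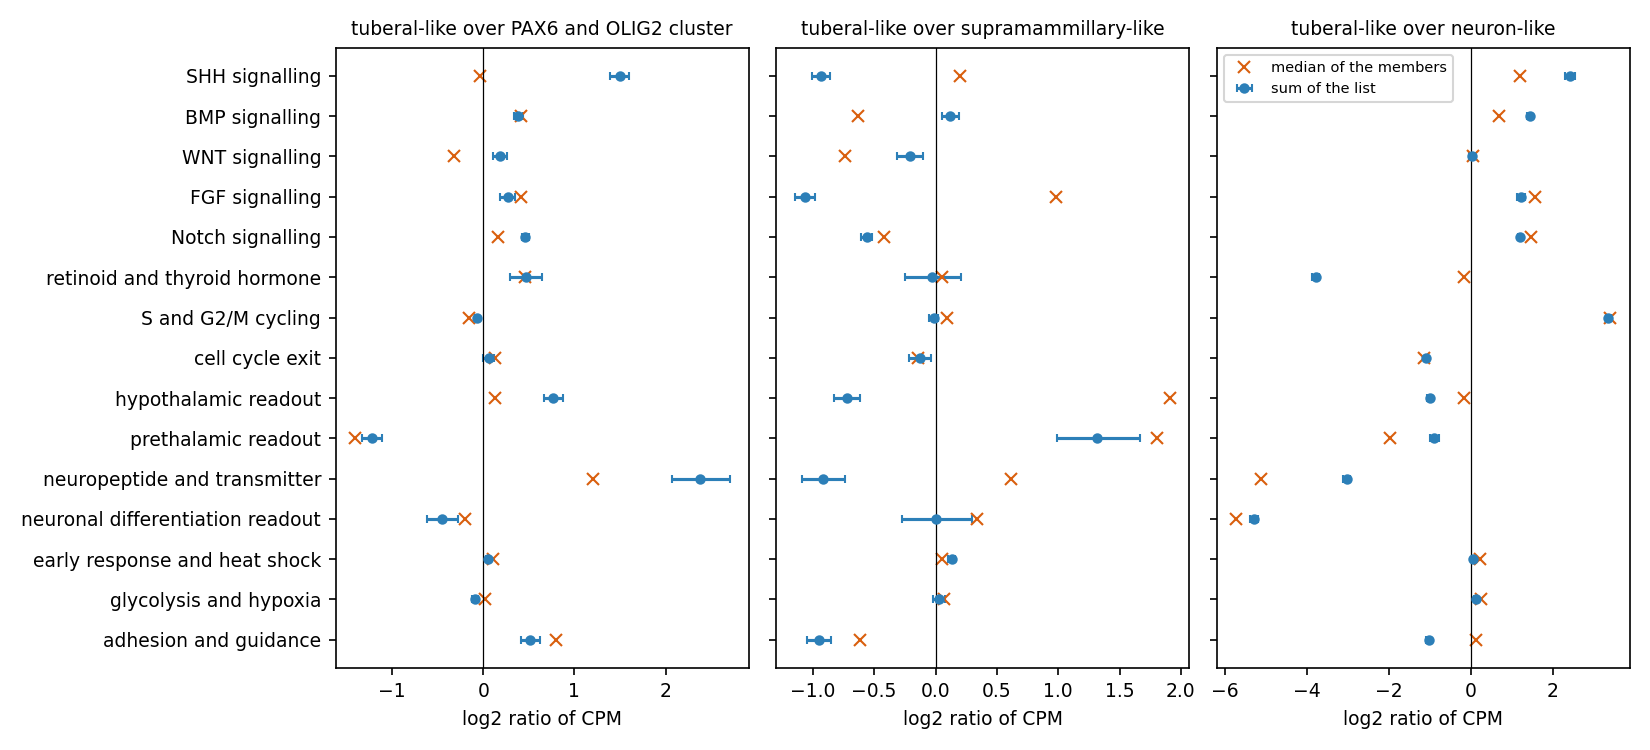
Log2 ratio of summed CPM (horizontal axis) of each gene list (vertical axis) in tuberal-like progenitors over cluster 3, supramammillary-like cells and neuron-like cells of HH18/19 replicate 1, with bars for exact 95% intervals and crosses for the median member. The midbrain and hindbrain list is not shown. SHH signalling has a sum of 1.497 but a median of -0.038 over cluster 3, and FGF signalling a sum of -1.06 but a median of 0.98 over supramammillary-like cells.

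The next comparison asked how tuberal and mammillary parts of the hypothalamus differ. No cluster met the rule for mammillary progenitors, which asked for 3 raised markers when only 4 were matched. The supramammillary-like cluster 10 therefore stood alone on that side. Cluster 1, with 645 of the tuberal-like cells, had the mammillary markers NKX2-1 and EMX2 raised, and NKX2-1 is also a tuberal marker. Mammillary-like cells on the tuberal side are thus not excluded. MEIS2, a homeodomain cofactor gene, had 447 UMIs in tuberal-like progenitors and 0 in supramammillary-like cells, and was at least 18.3-fold higher against the floor of 3 UMIs (interval from 14.8). FGF10 had 350 against 2 UMIs, a ratio of 21.5 (5.90 to 178.0) or 9.44 without cluster 1, VAX1 433 against 2 UMIs, a ratio of 26.6 (7.31 to 220), and FST, the follistatin gene, 308 against 1 UMI, a ratio of 37.8 (6.73 to 1497), all 3 near background. SHH was 2.08-fold (1.96 to 2.20) lower in tuberal-like progenitors, at 673 against 1398 CPM. RSPO2, an enhancer of WNT signalling, was 28.5-fold (19.3 to 43.1) lower, and GAL, the galanin gene, 19.0-fold (14.8 to 24.4) lower.

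In the SHH signalling list 5 of 8 genes were higher in tuberal-like progenitors and the median was 0.20, yet the sum was lower at a log2 ratio of -0.93 (-1.01 to -0.86). Without SHH it was -0.47 (-0.64 to -0.29). DISP1, needed for release of the SHH protein, was 11.2-fold (8.72 to 14.5) lower. Of 9 BMP signalling genes 6 were lower, with a median of -0.63, below every one of the random lists, while the sum was 0.12 (0.050 to 0.19). BMP7, a ligand, was 4.03-fold (2.70 to 5.92) lower and ID3 2.97-fold (2.55 to 3.45) lower, and ID1 was 2.98-fold (2.58 to 3.46) higher. The BMP sum turned to -0.21 (-0.28 to -0.13) without ID1, to -0.07 at a resolution of 0.6 and to -0.03 in cells with 3 or fewer Wpkci-7 UMIs.

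WNT signalling genes were lower in tuberal-like progenitors in 10 of 13 cases, with a median of -0.74, below all random lists, and a log2 ratio of -0.21 (-0.31 to -0.10). Besides RSPO2, AXIN2 was 6.52-fold (3.65 to 11.5) lower, while SFRP1, a secreted antagonist gene, was 5.41-fold (2.82 to 11.9) higher. The SFRP2 gene again held most of the list, and without it the ratio was -0.86 (-0.99 to -0.72), while without RSPO2 it was 0.003. At a resolution of 0.6 the WNT sum was -0.001, so its sign is weakly fixed. FGF signalling split sharply: 8 of 11 genes were higher, with a median of 0.98, above all random lists, but the sum was -1.06 (-1.15 to -0.98). The receptor gene FGFR3, 5.37-fold (4.99 to 5.77) lower at 223.1 against 1198 CPM, decided the sum, which was 0.76 (0.59 to 0.94) without it. FGF18, a ligand gene, had 278 against 3 UMIs, a ratio of 11.4 (3.85 to 55.5, near background). With clusters 5 and 7 added to cluster 10, the FGF sum was -0.37.

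Hypothalamic readout genes were higher in 7 of 9 cases with a median of 1.92, above all random lists, although the sum was -0.72 (-0.82 to -0.62). DBX1, at 228.4 against 728 CPM, decided it, and without DBX1 the ratio was 0.90 (0.67 to 1.13). SOX14, a transcription factor gene, had 97 UMIs against 0 and was at least 3.97-fold higher (interval from 3.17). All 4 prethalamic readout genes were higher, at 1.32 (0.99 to 1.66), among them ZIC1 with 81 against 1 UMI, a ratio of 9.94 (1.73 to 397.3, near background), or 3.60 (0.595 to 147.2) without cluster 11. Of 6 neuropeptide and transmitter genes 4 were higher and the median was 0.62, with HCRT, the orexin precursor gene, 4.17-fold (1.59 to 15.5, near background) and POMC 2.98-fold (1.12 to 11.1) higher. HCRT was at 3.93 CPM in supramammillary-like cells, and free RNA alone would add 4.10 CPM there. The sum was -0.91 (-1.09 to -0.74) because of GAL, and 0.55 (0.27 to 0.84) without it. PENK, the proenkephalin gene, was 2.17-fold (1.19 to 3.74) lower.

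Notch signalling genes were lower in 7 of 10 cases, at -0.56 (-0.61 to -0.52), with NOTCH2 2.31-fold (1.72 to 3.07) and the ligand JAG1 2.59-fold (1.51 to 4.29) lower and HEY1 2.60-fold (1.46 to 5.09) higher. Without HES5 the ratio was 0.042 (-0.049 to 0.14). Adhesion and guidance genes were lower in 8 of 12 cases, at -0.95 (-1.05 to -0.85). EPHA3 was 4.72-fold (4.13 to 5.40) and NCAM1, a neural adhesion molecule gene, 2.86-fold (2.41 to 3.38) lower, and CDH7 was 2.92-fold (1.22 to 9.16) higher, with a log2 ratio of -0.04 in cells with 3 or fewer Wpkci-7 UMIs. The supramammillary-like cells held 5 CDH7 UMIs in all, so this last value is not resolved. Retinoid and thyroid hormone genes were at -0.025 (-0.25 to 0.21), with 3 of 5 higher. DIO2, which encodes an enzyme that activates thyroid hormone, was 4.89-fold (3.002 to 7.84) lower and STRA6 2.17-fold (1.48 to 3.29) higher. The midbrain gene EN1 was 2.51-fold (1.20 to 4.89) lower, with 39 against 12 UMIs. Its list, with 63 against 17 UMIs, stood at -1.14 (-1.93 to -0.27), and at -0.76 (-2.18 to 0.98) without EN1. In cells with 3 or fewer Wpkci-7 UMIs the list had the opposite sign, at 0.54, a value that rests on few UMIs and has no interval.

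Ratios were small for S and G2/M cycling at -0.015 (-0.052 to 0.021), cell cycle exit at -0.13 (-0.21 to -0.04), neuronal differentiation at 0.004 (-0.28 to 0.30), early response and heat shock at 0.13 (0.10 to 0.16) and glycolysis and hypoxia at 0.027 (-0.023 to 0.076). NKX2-1 stood at 119.8 against 39.3 CPM, PAX6 at 7.83 against 2.95 CPM and SIX6 at 222.9 against 7.86 CPM, all 3 being clustering genes. The PAX6 ratio was 2.66 (0.870 to 13.2) and was not resolved at this depth, and without cluster 4 it was 0.636. Outside the lists, CAP2, RASSF3, ENSGALG00000041338, COL25A1 and ENO4 had 0 UMIs in supramammillary-like cells and were at least 4.46-fold to 2.66-fold higher in tuberal-like progenitors against the floor (intervals from 3.56 to 2.10). PLPPR5, BEGAIN, PTHLH, ABLIM1 and HUNK were lower by 10.5-fold to 4.35-fold. Cells with 6 or more Wpkci-7 UMIs made up 70.0% of the supramammillary-like cells.

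The last comparison set tuberal-like progenitors against neuron-like cells, to follow genes of proliferation and differentiation. GAD2, which encodes a GABA-synthesising enzyme, had 0 UMIs in tuberal-like progenitors and 130 in neuron-like cells, and was at least 108.4-fold lower in progenitors against the floor of 3 UMIs (interval from 86.9). The transcription factor genes EBF3 and ISL1 were 277.9-fold (145.8 to 609.5) and 261.3-fold (132 to 607.4) lower in progenitors, both near background, where they stood at 1.08 and 0.964 CPM and free RNA would add 0.784 and 0.869 CPM. NHLH1 was 134.9-fold (97.1 to 193.2) lower. PLK1 and CENPF, genes of mitosis, were 30.5-fold (16.0 to 66.9, near background) and 19.5-fold (16.3 to 23.5) higher. SHH was 9.38-fold (8.23 to 10.7) higher and GLI3, a Hedgehog pathway transcription factor gene, 26.6-fold (11.3 to 82.5) higher. NR5A1, a nuclear receptor gene of the ventromedial hypothalamus, was 45.3-fold (24.1 to 96.0) lower, with 180 of its 181 neuron-like UMIs in cluster 8.

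All 17 measured S and G2/M cycling genes were higher in progenitors, with a log2 ratio of 3.36 (3.30 to 3.42) and a median of 3.41, above all random lists. The ratio was 2.57 with doublets kept. Of the 10 Notch signalling genes 7 were higher, at 1.20 (1.15 to 1.25). The members that were lower were the ligands DLL1, 4.28-fold (3.72 to 4.93) or 1.91-fold without cluster 9, JAG2, 4.16-fold (3.35 to 5.17), and JAG1, 3.26-fold (2.34 to 4.56), while HEY1 was 6.35-fold (3.83 to 11.3) higher. All 4 cell cycle exit genes were lower, at -1.08 (-1.12 to -1.04), with GADD45A 4.62-fold (4.28 to 4.99) and BTG2, an antiproliferative gene, 3.002-fold (2.79 to 3.23) lower.

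Neuron-like clusters 9, 12 and 14 had more markers of other classes than of neurons among their leading genes, so values were also taken per cluster. The cycling log2 ratio was 3.53 over cluster 8, 3.03 over cluster 9, 3.91 over cluster 12, 3.68 over cluster 13 and 3.21 over cluster 14. The Notch ratio ranged from 0.46 over cluster 14 to 2.44 over cluster 12, and the cell cycle exit ratio from -1.29 over cluster 8 to -0.43 over cluster 13. Each of these lists kept its sign in all 5 clusters.

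SHH signalling genes were higher in progenitors in 8 of 8 cases, at 2.43 (2.30 to 2.56), and at 1.20 (1.03 to 1.38) without SHH. BMP signalling genes were higher in 8 of 9, at 1.44 (1.38 to 1.505), with ID4 8.16-fold (7.44 to 8.97) and FST 4.56-fold (3.07 to 7.04) higher, and at 0.54 (0.47 to 0.61) without ID4. FGF signalling genes were higher in 10 of 11, at 1.22 (1.13 to 1.32), with FGFR2 5.96-fold (4.32 to 8.43) and FGF18 5.85-fold (3.68 to 9.87) higher and FGF19 4.42-fold (3.41 to 5.75) lower. Of the 166 neuron-like UMIs of FGF19, 141 came from cluster 12, and without that cluster the ratio was 1.37 (0.872 to 2.22). FGF10 was 2.98-fold (2.19 to 4.13) higher, or 1.31-fold (0.898 to 1.93) without cluster 1. WNT signalling genes were at 0.040 (-0.030 to 0.11), with 9 of 15 higher. Among them NOTUM, a secreted WNT antagonist gene, had 73 against 0 UMIs and was at least 9.73-fold higher against the floor (interval from 7.71), and TCF7 was 6.07-fold (3.98 to 9.70) higher. Without SFRP2 the WNT ratio was -0.24 (-0.34 to -0.13).

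All 13 neuronal differentiation genes were lower in progenitors, at -5.28 (-5.38 to -5.19), and 10 of 11 neuropeptide and transmitter genes were lower, at -3.02 (-3.11 to -2.94). GAD1 had 3 against 152 UMIs, a 126.7-fold (42.5 to 621.3, near background) lower level. Its neuron-like UMIs too came mostly from clusters 12 and 14, with 270.2 CPM in cluster 12. SST was the 1 member that was not lower, at 108 against 83.2 CPM. Its progenitor level rested on cluster 1, at 204.7 CPM, and in clusters 4, 6 and 11 it was far below the neuron-like level. In the hypothalamic readout 7 of 13 genes were lower, at -0.996 (-1.06 to -0.93), while FEZF2, a zinc finger gene of the forebrain, was 4.68-fold (3.31 to 6.82) higher. Without NKX6-2, its member of highest level, that list stood at -0.34 (-0.41 to -0.26). In the prethalamic readout 6 of 9 were lower, at -0.88 (-0.99 to -0.77), with LHX1 65.9-fold (29.6 to 182.2) and SP9 61.5-fold (29.2 to 155.1, near background) lower, or 13.2-fold without cluster 14, and ZIC1 8.10-fold (3.04 to 30.4, near background) higher, or 2.93-fold without cluster 11. Both midbrain and hindbrain genes measured were lower, EN2 18.5-fold (11.1 to 32.8, near background) and EN1 5.71-fold (3.88 to 8.54), and the list stood at -3.29 (-3.71 to -2.88). The neuron-like clusters differed in EN2. It was found in 9.86%, 13.8% and 24.7% of thinned cells of clusters 9, 12 and 13, but in 1.61% and 0.0% of clusters 8 and 14.

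CRABP1, a retinoic acid binding protein gene, was 30.8-fold (28.4 to 33.6) lower in progenitors, or 7.88-fold lower without cluster 9, which held 6232 of its 7496 neuron-like UMIs. It decided the retinoid and thyroid hormone list. That list stood at -3.78 (-3.86 to -3.70) with it and at 0.45 (0.24 to 0.66) without it. Adhesion and guidance genes had a sum of -1.02 (-1.08 to -0.96) but 8 of 13 higher and a median of 0.12. NCAM1 was 9.07-fold (8.24 to 10.0) and CDH13 15.0-fold (7.87 to 31.5) lower, the last 3.79-fold without cluster 9, and without NCAM1 the list stood at -0.11 (-0.20 to -0.032). Early response and heat shock stood at 0.054 (0.037 to 0.071) and glycolysis and hypoxia at 0.12 (0.087 to 0.15).

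The clustering genes NKX2-1, PAX6 and SIX6 stood at 119.8 against 53.7 CPM, 7.83 against 23.8 CPM and 222.9 against 353.3 CPM, and the SIX6 log2 ratio of -0.67 was 0.11 in cells with 3 or fewer Wpkci-7 UMIs. Without neuron-like cluster 8 the SIX6 ratio was 5.09 (4.09 to 6.40). Outside the lists, CENPI, CDC7, ENSGALG00000004515, CCNB3 and CENPL, 4 of them genes of the cell cycle, were 31.1-fold to 25.4-fold higher in progenitors, all near background with intervals from 9.49 upwards. NYAP2, CNRIP1, TRAPPC3L, CACNA1B and ENSGALG00000025729 had 2 or 3 UMIs in progenitors and were lower by 110.0-fold to 58.4-fold, with intervals from 19.2 to 922.9 and all but CACNA1B near background. Cells with 6 or more Wpkci-7 UMIs made up 50.3% of neuron-like cells.

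Cells that hold transcripts of both NKX2-1 and PAX6 bear on the link between hypothalamic and prethalamic-like identity, and their count needs no clusters. With each of 3772 cells thinned to 2400 UMIs, 11.96% had an NKX2-1 UMI and 5.66% a PAX6 UMI. Both were found in 6.0 cells (mean of 100 thinnings), 0.159% (0.058 to 0.35%), against 25.5 cells, 0.677%, if the genes were independent. The ratio of observed to independent was 0.235 (0.086 to 0.51). In pairs within a marker set the ratio was 1.91 (1.61 to 2.25) for NKX2-1 with RAX and 1.88 (1.45 to 2.43) for PAX6 with OLIG2. For SIX6 with PAX6, a tuberal with a prethalamus marker like NKX2-1 with PAX6, it was 0.336 (0.183 to 0.588). NKX2-1 with OLIG2 stood at 1.22 (0.972 to 1.51) and SIX6 with OLIG2 at 0.683 (0.535 to 0.867).

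The background was low. In cluster 7, with a median of 5161.5 UMIs before thinning, 0.391% of cells had an NKX2-1 UMI and 0.469% a PAX6 UMI. The share of NKX2-1 was 22.2% in cluster 1, with a median of 6130 UMIs, and that of PAX6 was 22.4% in cluster 3, with a median of 5696 UMIs. PAX6 was also found in 14.4% of cluster 2, which held 79.9 of the 213.4 cells with a PAX6 UMI and had GBX2, IRX1, IRX2 and IRX3 raised, so the PAX6 cells of the ratio are not those of cluster 3 alone. Without thinning, 21 cells (0.557%) had both, against 83.6 if independent. With 2 UMIs needed for each gene, 0 of 3772 cells had both, against 0.916 if independent, too few to tell.

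Female birds carry a Z and a W chromosome, so UMIs of W-linked genes mark cells of female embryos in a library of mixed sex. Of the 3772 cells, 74.4% (73.0 to 75.8%) had 2 or more UMIs of Wpkci-7, SPIN1W and NIPBLL. Nearly all of these came from Wpkci-7 (ENSGALG00000035998), with 54380 UMIs against 192 and 689. Wpkci-7 split the cells: 57.6% (56.0 to 59.2%) had 6 or more UMIs with a median of 21, 39.0% (37.4 to 40.5%) had 3 or fewer, and 3.45% had 4 or 5. The cells with 3 or fewer had a mean of 1.15 UMIs, against 0.919 UMIs from free RNA. The share with 6 or more was 77.8% (74.4 to 81.0%) in cluster 1 and 18.6% (14.6 to 23.1%) in cluster 5.

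**Figure D3:**
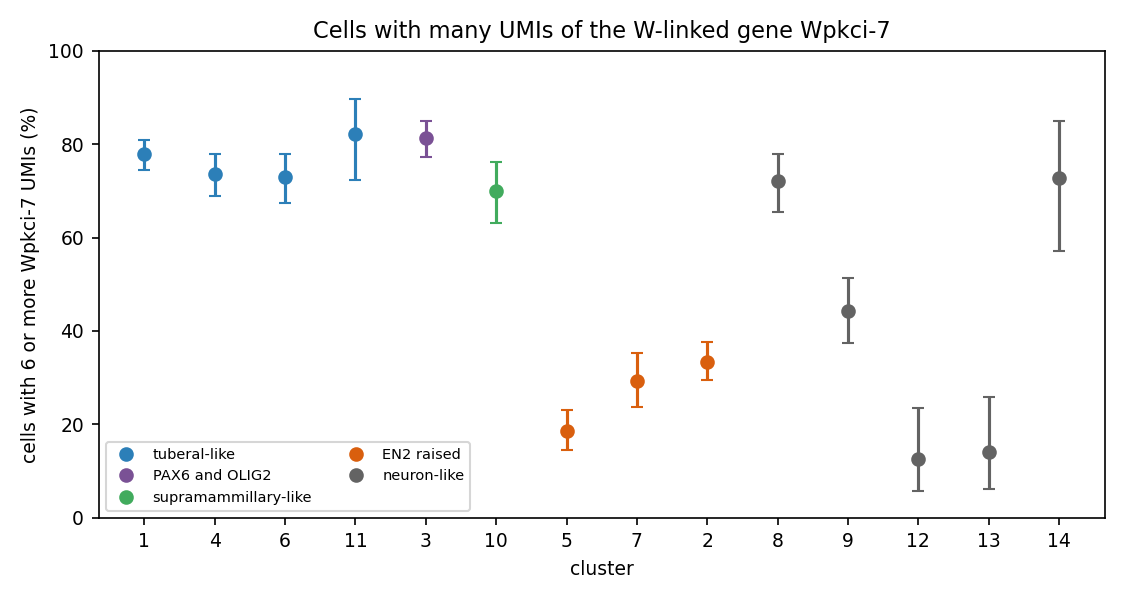
Share of cells with 6 or more Wpkci-7 UMIs (vertical axis, percent) in each cluster (horizontal axis) of HH18/19 replicate 1, coloured by class, with exact 95% binomial intervals. Clusters 2, 5 and 7, with EN2 raised, stand at 33.5%, 18.6% and 29.3%, and cluster 3 at 81.3%. Neuron-like clusters 9, 12 and 13, where EN2 was found in 9.86%, 13.8% and 24.7% of cells thinned to 2400 UMIs, stand at 44.3%, 12.7% and 14.0%.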

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

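The sets restricted by Wpkci-7, the neuron subset, the minimum of 6 W-linked UMIs, the added clusters 5 and 7, the lists without a gene and the averaging of co-detection over many thinnings were chosen after the data were seen. A total of 226 values were recomputed under alternative processing: 93 stayed within the counting interval of the reported value (for the number of cells, within 1.5-fold), 119 moved beyond it with the same direction or with none to keep, and 14 reversed. Where nothing else is said, the cause was not tested. No paired analysis was possible because 1 library with counts was analysed, so replicates could not be left out in turn either. The Z-linked part was not run because no annotation of the build was used here. A minimum of 1000 genes altered no value. Cluster borders were not stable: the adjusted Rand index against the reported clusters was 0.833 with another seed, 0.841 at a resolution of 0.6, 0.615 at 1.6, 0.768 with 4000 variable genes, 0.766 without the naming markers and 0.567 with the UMIs split. The order of the class shares and the signs of the WNT and FGF sums over PAX6 and OLIG2 cells and of the BMP and WNT sums over supramammillary-like cells are weakly fixed. The last of these, the WNT sum, stayed negative with the whole list but came to -0.001 at a resolution of 0.6 and -0.049 with another seed. The SHH sums over both of these classes, the BMP sum over PAX6 and OLIG2 cells, the FGF sum over supramammillary-like cells, and the Notch, cycling and cell cycle exit sums over neuron-like cells, kept their sign under every alternative that kept the whole list. Notch, cycling and exit sums of the other comparisons were not run under most of them. Depth limits genes with few UMIs in the 200 supramammillary-like cells.

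Log2 ratios below are of tuberal-like progenitors over the PAX6 and OLIG2 cells, the supramammillary-like cells or the neuron-like cells of each clustering. With at most 10% mitochondrial UMIs, 2404 cells were kept, with 8.29% supramammillary-like and 14.4% neuron-like cells. Ratios over PAX6 and OLIG2 cells were 1.61 (SHH), 0.48 (BMP) and 0.33 (WNT), over supramammillary-like cells -0.53 (SHH), -0.052 (WNT) and -0.68 (FGF), and over neuron-like cells 1.45 (Notch), 3.55 (cycling) and -1.001 (exit). With the threshold from the 6000 largest totals, the shares were 22.9% tuberal-like, 16.3% PAX6 and OLIG2 and 8.07% supramammillary-like. Ratios were then 0.625 (SHH), 0.525 (BMP), -0.138 (WNT, reversed) and -0.135 (FGF, reversed) over PAX6 and OLIG2 cells, -0.699 (SHH) and -0.845 (FGF) over supramammillary-like cells, and 0.965 (Notch) and -1.29 (exit) over neuron-like cells. Keeping doublets gave shares of 29.8% tuberal-like, 15.8% PAX6 and OLIG2 and 12.6% neuron-like. It gave ratios of 0.54 (SHH), -0.101 (WNT, reversed) and -0.02 (FGF, reversed) over PAX6 and OLIG2 cells and 1.145 (Notch), 2.57 (cycling) and -0.61 (exit) over neuron-like cells.

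With 4000 variable genes, the shares were 26.6% tuberal-like, 9.65% PAX6 and OLIG2, 3.87% supramammillary-like and 17.0% neuron-like. Ratios were 0.485 (BMP) and 0.18 (FGF) over PAX6 and OLIG2 cells, -0.38 (WNT) and -1.26 (FGF) over supramammillary-like cells, and 0.79 (Notch), 3.19 (cycling) and -1.29 (exit) over neuron-like cells. At a resolution of 0.6, the shares were 15.1% tuberal-like, 12.3% PAX6 and OLIG2 and 4.06% supramammillary-like. Ratios were 1.98 (SHH), 0.32 (BMP) and 0.42 (WNT) over PAX6 and OLIG2 cells, -0.41 (SHH), -0.069 (BMP, reversed) and -0.001 (WNT) over supramammillary-like cells, and 1.59 (Notch), 3.64 (cycling) and -0.92 (exit) over neuron-like cells. At 1.6, the shares were 28.3% tuberal-like, 9.38% PAX6 and OLIG2, 4.06% supramammillary-like and 12.4% neuron-like. Ratios were 0.46 (BMP) over PAX6 and OLIG2 cells, -1.08 (SHH) and -1.29 (FGF) over supramammillary-like cells, and 1.435 (Notch), 3.24 (cycling) and -0.53 (exit) over neuron-like cells.

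Another seed gave 34.9% tuberal-like and 7.87% supramammillary-like cells. It gave 1.615 (SHH), 0.49 (BMP), 0.402 (WNT) and 0.13 (FGF) over PAX6 and OLIG2 cells, -0.57 (SHH), -0.049 (WNT) and -0.71 (FGF) over supramammillary-like cells, and 1.35 (Notch) over neuron-like cells. Without the naming markers among the features, the supramammillary-like share was 8.01%. Ratios were 1.63 (SHH), 0.58 (BMP), 0.45 (WNT) and 0.165 (FGF) over PAX6 and OLIG2 cells, -0.74 (SHH), -0.067 (WNT) and -0.94 (FGF) over supramammillary-like cells, and 1.41 (Notch) over neuron-like cells. With the UMIs split between clustering and values, ratios were 0.32 (SHH), 0.53 (BMP), -0.059 (WNT, reversed) and -0.24 (FGF, reversed) over PAX6 and OLIG2 cells, -1.34 (FGF) over supramammillary-like cells, and 1.14 (Notch), 3.28 (cycling) and -1.24 (exit) over neuron-like cells. Subtracting free RNA gave 1.26 (Notch) and 3.91 (cycling) over neuron-like cells. The mean of per-cell CPM gave 0.33 (BMP) over PAX6 and OLIG2 cells and 1.04 (Notch) and 3.11 (cycling) over neuron-like cells.

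Cells with 6 or more Wpkci-7 UMIs gave 0.43 (BMP) over PAX6 and OLIG2 cells and -1.14 (exit) over neuron-like cells. Those with 3 or fewer gave 0.15 (BMP), 0.053 (WNT) and 0.15 (FGF) over PAX6 and OLIG2 cells, -1.015 (SHH), -0.03 (BMP, reversed) and -1.26 (FGF) over supramammillary-like cells, and 1.14 (Notch) and 3.48 (cycling) over neuron-like cells. Neuron-like cluster 8 alone, with SIX6 and CHRDL1 raised, gave 1.55 (Notch), 3.53 (cycling) and -1.29 (exit). With clusters 5 and 7 added to the supramammillary-like cells, ratios were -0.555 (SHH), 0.63 (BMP) and -0.37 (FGF). Lists were also taken without the gene of highest level and without the gene whose removal moved the sum most towards or past 0. Over PAX6 and OLIG2 cells, they gave -0.27 without SHH (reversed), 1.47 (BMP) without ID1, -0.445 (BMP) without ID4 (reversed), -0.34 (WNT) without SFRP2 (reversed), 0.43 (FGF) without FGFR3 and 0.17 (FGF) without ETV5. Over supramammillary-like cells they gave -0.47 without SHH, -0.21 (BMP) without ID1 (reversed), -0.86 (WNT) without SFRP2, 0.003 (WNT) without RSPO2 (reversed) and 0.76 (FGF) without FGFR3 (reversed). Over neuron-like cells they gave 0.90 (Notch) without HES5, 3.24 (cycling) without TOP2A, -1.48 (exit) without BTG1 and -0.84 (exit) without GADD45A. In these the removed gene is itself the cause. Co-detection of NKX2-1 and PAX6 was 0.557% without thinning, where deeper cells show more UMIs, and 0.0% with 2 UMIs of each gene, where 0.916 cells were expected of independent genes. The share of cells with W-linked UMIs was 88.5% at a minimum of 1, 65.5% at 3 and 57.8% at 6.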

Other observations

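All values and tests in this part were chosen after the data were seen, except the test of clusters formed on sex-linked genes. The neuron-like clusters differed in their transmitter and peptide genes. Cluster 8 (218 cells) carried HCRT, the orexin precursor gene, at 1265 CPM (1206 to 1326), NPY at 623.9 CPM (582.8 to 667), PENK at 214.2 CPM (190.5 to 240.1), POMC at 191 CPM (168.6 to 215.5) and NR5A1 at 130.7 CPM (112.3 to 151.3). Cluster 9 (210 cells) carried CRABP1 at 5527 CPM (5391 to 5666), OTP and SIM1, transcription factor genes of neuroendocrine neurons, at 225.3 and 105.5 CPM, and AVP, the gene of vasotocin in birds, at 58.5 CPM (45.3 to 74.5). Genes of GABA synthesis and loading marked clusters 12 and 14: GAD1 at 270.2 and 163.2 CPM, GAD2 at 186.8 and 320.9 CPM, and SLC32A1 at 386.9 and 168.6 CPM. Cluster 14 (44 cells) also carried DLX5 at 636.4 CPM and SP9 at 745.2 CPM, genes of prethalamic GABA neurons. It had all 5 matched prethalamus markers raised, but also the tuberal markers NKX2-1, SIX6 and CHRDL1. NKX2-1 was found in 27.95% (14.96 to 42.79%) and PAX6 in 9.09% (2.53 to 21.67%) of its thinned cells. Whether single cells of this cluster held both was not tested. Cluster 12 (63 cells) carried LHX1 at 220.1 CPM. The leading genes of cluster 12 were TAL2 at 2488 CPM against 15.6 CPM in all other cells, TAL1 at 590.4 against 0.659 CPM and GATA2 at 480.3 against 0.800 CPM. It also had IRX1 and IRX2, markers of thalamus or more caudal brain, raised, and EN2 in 13.8% of thinned cells. Its place of origin was not tested. Cluster 13 (57 cells) carried EBF3 at 756.4 CPM, ISL1 at 689.6 CPM and NEFL at 947.8 CPM.

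The tuberal-like progenitors were not uniform. SHH was at 409.7 CPM (390.7 to 429.4) in cluster 1, at 1034 CPM in cluster 4 and at 1012 CPM in cluster 6, while FGF10 was at 64.6 CPM (57.2 to 72.7) in cluster 1 and at 19.4 and 21.1 CPM in clusters 4 and 6. FGF8, an FGF ligand of several signalling centres, was at 453.9 CPM (388.8 to 526.8) in cluster 11 and at 314.8 CPM (295.1 to 335.4) in cluster 2, against 4.70 CPM in cluster 1. Within tuberal-like progenitors, cells with 3 or fewer Wpkci-7 UMIs had higher levels of a set of genes that includes CETN3 at 2.17-fold (1.83 to 2.57), ATP5A1Z at 1.91-fold (1.80 to 2.04) and SMAD2Z at 1.84-fold (1.49 to 2.26). These genes were picked by their ratios, and their chromosomes were not analysed here.

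The share of cells with 6 or more Wpkci-7 UMIs was 28.2% (25.6 to 30.8%) in clusters 2, 5 and 7, with EN2 raised, and 70.5% (68.7 to 72.2%) in all others together, although among these neuron-like clusters 9, 12 and 13, with EN2 in 9.86%, 13.8% and 24.7% of thinned cells against at most 0.513% from free RNA, had 44.3%, 12.7% and 14.0%. Clusters formed on sex-linked genes are argued against by gates on single genes: cells with a SIX6 or RAX UMI and no EN1 or EN2 UMI had a share of 74.4%, those with an EN1 or EN2 UMI and no SIX6 or RAX UMI 27.3%, a difference of 47.03 percentage points. Depth of the cells is argued against as well, since with every cell thinned to 2400 UMIs the shares with 2 or more Wpkci-7 UMIs were 75.2% and 38.9%, a difference of 36.25 points; a first version on 2 clusters was replaced by this test. Unequal numbers of female and male embryos in separate dissections, or a difference between the sexes in the size of regions, stay open and were not tested, and no biological explanation was tested. With 1 library and no map of cells to embryos these cannot be separated.

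EN1 and EN2, homeodomain genes of midbrain and anterior hindbrain, had UMIs in a library labelled hypothalamus, at 108.7 and 230.5 CPM in cluster 2, 106 and 193.5 CPM in cluster 5, and 312.8 and 198.4 CPM in cluster 7. Free RNA is argued against, since the EN2 level in cluster 2 was 126.2 times the level that free RNA adds. A candidate explanation is cells of more caudal brain in the dissected tissue: EN1 or EN2 was found together with SIX6 or RAX at 0.2288 (0.162 to 0.311) of the frequency expected of independent genes, which is what separate cells would give. GBX2, a gene of the anterior hindbrain and thalamus, was at 67.2 CPM and PAX5 at 33.9 CPM in cluster 2, while FOXA2, a floor plate gene, was at 155.2 and 226.6 CPM in clusters 5 and 7. The same low co-detection would arise from EN2 cells within the hypothalamus itself, so their place of origin stays open.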
